A study of Mus musculus with 4 samples.

How the data were processed

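RNA was sequenced from 4 mouse samples, 1 per combination of site (facial skin or oral mucosa) and wound state (unwounded or day 7). Per the labels' protocols, the tissue was digested with collagenases, and sorted samples were stained for lineage markers before RNA sequencing by an outside company. The authors deposited 1 table of whole-number counts per gene symbol. Per the submitters' processing notes, the genome build was mm10 and the tools included TopHat2 version 2.0.13, DESeq and DESeq2; the role of each, the program that counted reads and the gene annotation are not given in the sources used here.

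Groups were taken from the sample descriptions. A column of the table was given to a sample only where its name matched that sample's labels and no other sample's, with case and punctuation ignored. All 4 columns failed this rule and entered no comparison, so no normalization, filter, ratio between groups or test was computed. The fold comparisons, gene lists and additive edgeR fits that had been fixed before the data were examined were not run. The values of the columns were inspected to establish their unit. Column totals and the reads of some genes were seen in this step. Actb, Gapdh and Col1a1 were among several genes with very few reads in every column. That left a doubt, not tested here, over whether the gene symbols belong to the counts beside them. A key from columns to samples would not settle this doubt.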

Results

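The series profiled RNA from mouse cells of facial skin and oral mucosa, tissues whose wounds were to be compared. The labels describe the cells as lineage-negative fibroblasts of the genotype Wnt1ER mTmG. The sorting panel named in the labels recognises Tie2 and CD31 on endothelium, CD45 on leukocytes, CD324 and CD326 on epithelium, and Ter119 on red cells. The 4 samples crossed site with wound state, with 1 library each from unwounded facial skin, unwounded oral mucosa, facial wounds at day 7 and oral wounds at day 7. With 1 library per group, the design held no replicate of any group.

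The design implies 4 comparisons between libraries. Oral mucosa can be set against facial skin in the unwounded state and at day 7, and day 7 can be set against the unwounded state at each site. A difference between the wound responses of the sites follows from these. None of these comparisons was made here. The authors' table of gene counts has 4 columns, and 0 of them had a name that matched the labels of 1 sample. The column names are codes that give neither a site nor a wound state. They carry 2 different combinations of a leading code and a lane number, with 2 columns each. If the columns are the 4 libraries of the design, this split coincides with site, with wound state or with their interaction. A key from columns to samples would show which of these cannot be told apart from the leading code and lane, without separating them. What the leading code stands for was not established. Columns were not placed by their order, which carries no label, or by their values, which would build the outcome into the groups. Accordingly, no gene, gene group or cell type is reported as higher or lower in any group, and no depth is given for any group. Even with a key, statements about genes would first need the doubt over the gene symbols to be settled.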

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

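The only result, 0 of 4 columns matched to 1 sample, was the same under 2 other matching rules. Both rules were chosen after the column names were seen. These were any shared word of at least 3 characters in the title, description, source or characteristics, and any such word in any label field, protocols included. The main rule was not among the steps fixed beforehand either. A word shared with more than 1 sample counted as no match. As the names were already known to be codes, the agreement adds no support to the result. The alternatives fixed before the data were examined were not run, because each needs columns placed in groups: other normalizations, filters on low counts, pseudocounts and thresholds of size, the fits without marker genes, DESeq2 in place of edgeR, and the fits without a covariate. Leaving out each replicate in turn was not run either, since each group has 1 library.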
